A study of Arabidopsis thaliana with 6 samples.

How the data were processed

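Messenger RNA was profiled by RNA-seq in wild-type Arabidopsis thaliana seedlings of the Col-0 accession. N-linolenoylethanolamine (NAE 18:3) is an N-acylethanolamine, a fatty acid amide of ethanolamine, here that of linolenic acid. Seedlings were placed in liquid medium with sucrose that held NAE 18:3 at 100 µM or, as the solvent control, DMSO at 0.07%, and were harvested after 1 h. The labels do not record how much DMSO the NAE 18:3 medium held, so a difference in solvent between the groups cannot be ruled out. The growth text gives the age at transfer as 3 days, while the treatment text and the age label give 4 days. Each group had 3 libraries, and the labels call them biological replicates. The labels record no date, plate or sequencing lane, so any unrecorded batch that followed the treatment cannot be separated from it.

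Reads were processed by the authors with TopHat, Cufflinks and Cuffdiff against the TAIR9 build, per the submitters' processing notes, which list no versions or settings. The deposited table lists 61448 assembled transcripts of 32424 loci, with an FPKM value (fragments mapped to a transcript, scaled by its length and by the fragments mapped in the library) for each transcript and each locus in every library. The unit is not written in the column headers. It was taken from the processing notes and from the values, which were not whole numbers, and the transcript values added up to the locus value within a relative tolerance of 0.001 for 32423 of 32424 loci. For AT1G52825 the transcript columns of 1 entry held text in place of numbers, and its locus values were used. Columns were matched to libraries through the sample descriptions, and 4 further columns headed as merged values were not used. The table held none of the authors' own fold changes or p-values among the columns analysed, so the planned comparison with them was not run.

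FPKM is already scaled for length and library, so no total count per library can be read from it. Low FPKM values rise in steps of 1 fragment, and comparing those steps at loci under 0.3 FPKM gave the depth of each library relative to NAE 18:3 replicate 1, together with any scaling that Cuffdiff applied. This relative depth was 0.482, 0.753 and 0.968 for DMSO replicates 1, 2 and 3, and 0.987 and 1.27 for NAE 18:3 replicates 2 and 3. The absolute depth is unknown, so no counting intervals are given. Of the loci compared, 22.8% to 31.7% lay at the common step, so whole fragments could not be recovered for every locus and no count model was applied.

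Loci were named through their TAIR gene identifiers, and symbols and products came from the TAIR10.1 annotation, in which 31583 of the 32319 TAIR gene identifiers were found. Because the builds differ, that annotation served for names, products and gene lengths only, and no coordinates are given. The assembly joined several TAIR genes in 644 loci, and the values of such loci cannot be divided between their genes. A further 605 TAIR genes were spread over several loci, and 179 loci had no TAIR gene. The 130 chloroplast-encoded and 141 mitochondrial loci were all listed at 0 in all 6 libraries, so the planned comparison of organelle transcript shares could not be run. Values of families with near-identical copies, such as LHCB, RBCS, AOC and the small heat shock proteins, are uncertain between copies.

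Loci with a mean of at least 1 FPKM over the 6 libraries were tested, which left 18194. Log2(FPKM + 1) values were fitted with limma 3.58.1 in R 4.3.3, with group as the only term and a mean-variance trend in the empirical Bayes step. A locus was called changed at a Benjamini-Hochberg adjusted p under 0.05. Log2 changes are NAE 18:3 minus DMSO on the log2(FPKM + 1) scale, which understates the change of loci near 0. Gene lists of at least 3 tested loci were compared with all other loci by camera with a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. P-values were adjusted over the 29 lists. These 29 lists were fixed before the data were examined, 1 of them by a rule that took every gene described as a 40S or 60S ribosomal protein, either in the deposited table or in the annotation. That wording took 12 genes, as many ribosomal protein genes are described without 40S or 60S. Further lists were drawn up after the largest changes had been seen, leaving out the loci seen. Of these, 6 were tested, and 1 more, of iron-deficiency genes, had only 2 loci past the filter and was not.

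Genes are named by a rule fixed in advance. It takes the 12 largest rises and the 12 largest falls among called loci whose groups did not overlap. From each list it takes up to 2 members that rose and 2 that fell with the smallest adjusted p, or the 2 with the highest mean where fewer than 2 passed. It adds the gene of fatty acid amide hydrolase, all heterotrimeric G protein genes, and the reference genes as a range. Called list members whose log2 change turned in sign with another scaling are named beside their list, and other genes named outside the rule were chosen after their values were seen.

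The fit was tested on simulated values for the DMSO against NAE 18:3 comparison over 18194 loci, with the spread of the real libraries. It recovered 61.2% of loci changed by 0.5 on the log2 scale, 92.5% of those changed by 1 and 97.0% of those changed by 2, and 3 of 170 calls were false. Only 67, 67 and 66 loci were given those changes, up and down alike, with no scaling difference between the groups. In the real libraries 83.2% of loci were called, so these rates do not carry over to them. Alternatives covered a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, quantile normalization and upper-quartile scaling. They also covered no trend, a robust trend, a replicate block, each library left out in turn, a stricter threshold, transcripts summed per TAIR gene, and loci over several TAIR genes left out. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.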

Results

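The transcriptomes of seedlings exposed for 1 h to 100 µM NAE 18:3 were compared with those of seedlings kept in 0.07% DMSO, with 3 libraries per group. The question was which transcripts differ after a short exposure to this polyunsaturated N-acylethanolamine. Summed FPKM over all loci was 866221, 697722 and 688025 in the DMSO libraries and 1140300, 991483 and 1023180 in the NAE 18:3 libraries. Part of the sum of replicate 1 in each group came from a locus with an extreme value there. AT3G08520, a short ribosomal protein gene, stood at 172116 FPKM in DMSO replicate 1, 19.9% of that library's sum, against 76.2 and 73.7 FPKM in the other DMSO libraries. AT2G07748, a tRNA gene, stood at 130702 FPKM in NAE 18:3 replicate 1 and was listed at 0 in the other 5. Without these loci the sums were 694105, 697645 and 687951 in DMSO and 1009580, 991458 and 1023150 in NAE 18:3. The difference between the groups therefore remained. The 10 most abundant loci held 14.8% and 15.3% of the sum in NAE 18:3 replicates 2 and 3, against 8.48% and 8.39% in DMSO replicates 2 and 3. The shallowest library was DMSO replicate 1, at 0.482 of the depth of NAE 18:3 replicate 1.

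Transcript levels differed between the groups across most of the expressed genome. Of 18194 loci tested, 15143 changed, 83.2% of them all, with 8018 higher and 7125 lower after NAE 18:3 (limma, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold changes were found for 6480 loci, 3347 higher and 3133 lower. The 3 values of one group lay wholly outside those of the other at 84.6% of loci, where chance alone gives 10%. Across loci, Pearson's r was 0.988 to 0.991 between DMSO libraries, 0.991 to 0.994 between NAE 18:3 libraries and 0.765 to 0.776 between groups, with loci not being independent replicates. The first principal component separated the groups and held 95.1% of the variance. The split between directions depended on scaling. With each library brought to one upper quartile, 5857 loci were higher and 9497 lower, and the median log2 change of all loci moved from 0.06 to -0.25. Values below are on the deposited scale, and small changes are to be read against that shift.

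On the log2(FPKM + 1) scale the largest rise among called loci was that of ASN1 (AT3G47340), the dark-inducible gene of glutamine-dependent asparagine synthase 1, which went from 0.426 ± 0.149 FPKM to 869 ± 20.7 FPKM (mean ± SD, n = 3 each). Its log2 change was 9.26 with a standard error of 0.07 (limma, Benjamini-Hochberg adjusted p = 1.5e-11). AT2G44130, encoding a kelch-repeat protein, was listed at 0 in the 3 DMSO libraries and stood at 472 ± 13.9 FPKM after NAE 18:3, and it passed ASN1 with a pseudocount of 0.1. AT3G15450, encoding an aluminium-induced protein with YGL and LRDR motifs, rose from 5.02 ± 0.65 to 1939 ± 20.4 FPKM. BCAT-2 (AT1G10070), a branched-chain amino acid transaminase, rose from 0.36 ± 0.188 to 264 ± 5.6 FPKM, and THA1 (AT1G08630), threonine aldolase 1, from 0.932 ± 0.299 to 318 ± 7.63 FPKM. AT1G21400, a thiamin diphosphate-binding protein, rose from 0.743 ± 0.11 to 213 ± 1.28 FPKM. BT1 (AT5G63160), a BTB and TAZ domain protein, rose by 7.06 on the log2 scale. AT2G05540, a glycine-rich protein, rose by 7.35, and AT2G33830, a dormancy/auxin associated protein, by 6.92. The last of the 12 were AT2G20670, AT4G20860 and AT3G22060, with log2 changes of 6.67, 6.47 and 6.45. For AT4G20860, a berberine-type FAD-binding protein, the DMSO libraries ranged from 0.00064 to 6.79 FPKM.

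Among the 12 largest falls, CHS (AT5G13930), chalcone synthase, the entry enzyme of flavonoid synthesis, fell from 491 ± 15.3 to 15.1 ± 1.17 FPKM (log2 change -4.94, standard error 0.05, limma with Benjamini-Hochberg adjusted p = 3.5e-11). DFR (AT5G42800) fell from 46.9 ± 3.29 to 0.544 ± 0.199 FPKM, LDOX (AT4G22880) from 56.5 ± 1.72 to 0.882 ± 0.107 FPKM, and GSTF12 (AT5G17220), a glutathione transferase needed for anthocyanin accumulation in vacuoles, from 56.0 ± 4.56 to 0.615 ± 0.168 FPKM. GPT2 (AT1G61800), a plastid glucose-6-phosphate translocator induced by sugar, fell from 171 ± 6.14 to 3.16 ± 0.456 FPKM. AGP30 (AT2G33790), a root arabinogalactan protein, fell from 72.5 ± 7.72 to 0.494 ± 0.188 FPKM. ESM1 (AT3G14210), a modifier of glucosinolate hydrolysis, fell from 163 ± 1.94 to 3.17 ± 0.928 FPKM. CRA1 (AT5G44120), a cruciferin seed storage protein, fell from 40.8 ± 8.69 to 0.437 ± 0.123 FPKM. The remaining falls were those of AT5G26220, a ChaC-like protein (log2 change -5.39), PDF2.5 (AT5G63660), a defensin-like protein (-5.32), and AT1G73600, a methyltransferase (-5.01). SNOR108 (AT5G41471), a small nucleolar RNA gene of 110 bp, stood at 276 ± 65.2 FPKM in DMSO and was listed at 0 in the 3 NAE 18:3 libraries. FPKM of genes this short is uncertain.

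**Figure D1:**
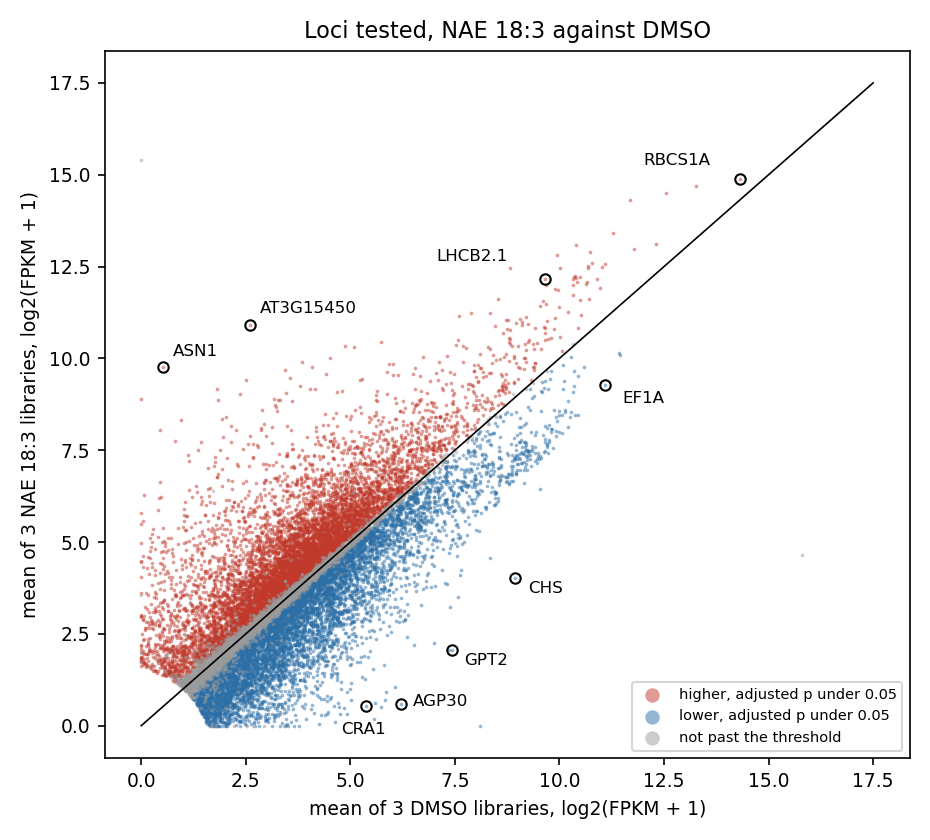
Log2 of the mean FPKM plus 1 for the 3 DMSO libraries (x axis) against that for the 3 NAE 18:3 libraries (y axis). The 18194 loci tested are higher (red), lower (blue) or not past an adjusted p of 0.05 (grey), with a line of equal values. ASN1 and AT3G15450 lie far above the line, and CHS, GPT2, AGP30 and CRA1 far below it.

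Genes of rapid stress responses rose together. Of 25 tested early stress transcription factors, 25 rose, all at least 2-fold, with a median log2 change of 3.24 (camera adjusted p = 1.0e-08, and adjusted p = 0.128 with an estimated correlation). ZAT12 (AT5G59820), a zinc finger protein of oxidative and abiotic stress, rose from 4.9 ± 0.329 to 202 ± 7.46 FPKM, and ZAT6 (AT5G04340) from 3.9 ± 0.272 to 138 ± 4.27 FPKM. The 9 calcium-binding and touch genes all rose, with a median of 3.42 (camera adjusted p = 0.00061, and adjusted p = 0.186 with an estimated correlation). XTH22 (AT5G57560), the touch gene TCH4 that encodes a xyloglucan-modifying enzyme, went from 16.9 ± 1.09 to 579 ± 7.37 FPKM, and CML12 (AT2G41100), the calmodulin-like protein TCH3, from 57.6 ± 3.15 to 795 ± 17 FPKM. For these and the other lists, the count of members that rose or fell was also taken adjusted over the list alone, and it differed from the count over all loci for 0 of 29 lists. With 83.2% of all loci called, both adjustments have nearly the same cutoff, so this adds no support. Over all loci tested 44.1% were higher and 39.2% lower, against which the counts per list are to be read.

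Of 17 tested detoxification loci 15 rose, 1 fell and 1 did not pass, with a median of 2.099 (camera adjusted p = 0.00035, and adjusted p = 0.128 with an estimated correlation). The locus that joins the oxophytodienoate reductase genes OPR1 and OPR2 rose from 19.3 ± 0.619 to 288 ± 18.1 FPKM. GSTU5 (AT2G29450), a glutathione transferase, rose from 48.6 ± 3.48 to 556 ± 13.1 FPKM, whereas GSTU10 (AT1G74590) fell by 0.83 on the log2 scale. The joined locus of GSTF6 and GSTF7 rose slightly, and it was lower with upper-quartile scaling. Of 15 heat shock loci 13 rose, 1 fell and 1 did not pass, with a median of 1.70 (camera adjusted p = 0.00086, and adjusted p = 0.128 with an estimated correlation). DREB2A (AT5G05410), a drought and heat transcription factor, rose from 1.05 ± 0.023 to 67.2 ± 1.1 FPKM and HSP90.1 (AT5G52640), a cytosolic chaperone, from 41.3 ± 1.87 to 201 ± 1.78 FPKM. ROF1 (AT3G25230) stood at 72.8 ± 1.81 and 67.9 ± 2.45 FPKM, a log2 change of -0.10 that passed narrowly (limma, Benjamini-Hochberg adjusted p = 0.039) and was lost in 6 of the alternatives. The joined locus of HSP18.2 turned from higher to lower with either of the other scalings.

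Of 16 pattern-triggered immunity genes 11 rose, 1 fell and 4 did not pass, with a median of 1.11 (camera adjusted p = 0.013, and adjusted p = 0.186 with an estimated correlation). PHI-1 (AT1G35140), a phosphate-induced protein, rose by 4.44 on the log2 scale and BIK1 (AT2G39660), a receptor-associated kinase, by 3.05. CYP79B2 (AT4G39950), an enzyme of indole glucosinolate and camalexin synthesis, fell from 23.7 ± 1.89 to 4.57 ± 0.178 FPKM. PEPR1 of this list and GSTU2 of the detoxification list were not analysed here. The salicylic acid list was not called as a group (7 rose and 2 fell of 9, median 1.23, camera adjusted p = 0.079). In it the salicylic acid receptor gene NPR3 (AT5G45110) rose by 2.17 and CBP60G (AT5G26920) by 2.56, while EDS5 (AT4G39030), a transporter for the salicylic acid pathway, fell by 1.04 and ICS1 (AT1G74710), isochorismate synthase, fell by 0.22. The oxidative stress and mitochondrial retrograde list was not called either (5 rose, 2 fell and 1 did not pass of 8, median 0.79, camera adjusted p = 0.22). AOX1A (AT3G22370), the mitochondrial alternative oxidase, rose from 12.3 ± 0.776 to 95.1 ± 4.61 FPKM and BCS1 (AT3G50930) from 3.57 ± 0.034 to 33.9 ± 1.02 FPKM. The superoxide dismutase genes FSD1 (AT4G25100) and CSD1 (AT1G08830) fell by 0.48 and 0.33.

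Jasmonate genes moved in both directions. Of 15 jasmonate biosynthesis genes 12 rose and 3 fell, with a median of 1.02 (camera adjusted p = 0.049, and adjusted p = 0.433 with an estimated correlation), of which ACX1 and OPR3 turned from higher to lower with either of the other scalings. The call was also lost with at least 5 FPKM, quantile normalization (median 0.65), the replicate block, transcripts summed, joined loci left out and 3 of the libraries left out singly. AOC3 (AT3G25780) and AOC1 (AT3G25760), allene oxide cyclases, rose by 2.84 and 2.61 on the log2 scale. LOX2 (AT3G45140), the chloroplast lipoxygenase of wound-induced jasmonate synthesis, fell from 39.5 ± 1.69 to 1.4 ± 0.0578 FPKM, and AOC4 (AT1G13280) from 43.7 ± 1.02 to 11.05 ± 0.798 FPKM. Of 19 jasmonate signalling and turnover genes 15 rose, 3 fell and 1 did not pass, with a median of 1.26 (camera adjusted p = 0.0083, and adjusted p = 0.158 with an estimated correlation), COI1 being lower with upper-quartile scaling and IAR3 with either of the other scalings. JAZ9 (AT1G70700), a jasmonate repressor, rose from 8.05 ± 0.711 to 107 ± 2.81 FPKM and ILL6 (AT1G44350), a jasmonoyl-isoleucine hydrolase, from 7.7 ± 0.356 to 39.6 ± 0.659 FPKM. VSP2 (AT5G24770), a vegetative storage protein commonly used as a jasmonate marker, fell by 1.25 and the transcription factor gene ORA59 (AT1G06160) fell by 0.57.

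The other hormone lists were mixed and not called as groups. Of 24 abscisic acid genes 13 rose, 10 fell and 1 did not pass, and their median of 0.20 turned to -0.12 with upper-quartile scaling, in which ABF2 and OST1 went from higher to lower (camera adjusted p = 0.537). RD29A (AT5G52310), a desiccation and cold gene, rose from 21.7 ± 1.23 to 215 ± 2.12 FPKM, and CYP707A3 (AT5G45340), an abscisic acid hydroxylase, by 2.92, while RD22 (AT5G25610) fell by 1.37 and EM1 (AT3G51810), a late embryogenesis protein, by 2.70. Of 15 ethylene genes 9 rose, 3 fell and 3 did not pass (median 0.42, camera adjusted p = 0.16). With upper-quartile scaling 7 of them rose, 6 fell and 2 did not pass (median 0.08). With quantile normalization 8 rose, 4 fell and 3 did not pass (median 0.13). ACO4 (AT1G05010) rose from 75.9 ± 4.55 to 460.5 ± 9.49 FPKM. ACO1 (AT2G19590), of the same family of ethylene-forming oxidases, fell from 34.8 ± 1.5 to 2.33 ± 0.367 FPKM at its most abundant locus. ACS7 (AT4G26200), an ACC synthase, rose by 3.39, and the ethylene receptor gene ETR2 (AT3G23150) fell by 0.99. Of 17 auxin genes 6 rose, 5 fell and 6 did not pass, and their median of 0.13 turned to -0.16 with upper-quartile scaling, in which IAA3 went from higher to lower (camera adjusted p = 0.975, with a downward direction against the upward median). IAA2 (AT3G23030) and GH3.5 (AT4G27260) rose by 2.66 and 2.09, and the auxin transporter gene PIN7 (AT1G23080) fell by 0.57. Of 6 type-A response regulators of cytokinin signalling 4 rose, 1 fell and 1 did not pass (median 0.71, camera adjusted p = 0.34). Among them ARR7 (AT1G19050) and ARR5 (AT3G48100) rose by 1.96 and 0.85, and ARR16 (AT2G40670) fell by 1.12. In the CBF cold regulon, which shares RD29A with the abscisic acid list, 4 of 5 rose and 1 did not pass (median 1.46, camera adjusted p = 0.054). COR47 (AT1G20440), a dehydrin, rose from 92.8 ± 1.66 to 861 ± 41.4 FPKM.

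Genes that bear on the compound itself changed moderately. FAAH (AT5G64440), fatty acid amide hydrolase, which cleaves N-acylethanolamines, stood at 16.1 ± 0.56 FPKM in DMSO and 25.9 ± 0.276 FPKM after NAE 18:3, higher in 3 of 3 libraries, a log2 change of 0.65 with a standard error of 0.04 (limma, Benjamini-Hochberg adjusted p = 1.2e-06). Of 13 acylethanolamide, phospholipase D and oxylipin genes 10 rose, 2 fell and 1 did not pass, with a median of 0.65 (camera adjusted p = 0.044, and adjusted p = 0.186 with an estimated correlation), a call also lost with at least 5 FPKM and with the block. The median of this list was 0.31 with upper-quartile scaling and 0.43 with quantile normalization. DOX1 (AT3G01420), an alpha-dioxygenase, rose from 10.7 ± 0.529 to 32.0 ± 0.628 FPKM and FAD7 (AT3G11170), a plastid omega-3 desaturase, from 95.9 ± 6.03 to 253 ± 1.3 FPKM. FAD3 (AT2G29980), the omega-3 desaturase of the endoplasmic reticulum, fell by 1.06 and LOX1 (AT1G55020) by 0.32. Of 9 heterotrimeric G protein genes 7 rose and 2 fell, and the list was not called (median 0.82, camera adjusted p = 0.089). The log2 change was 0.82 for the alpha subunit gene GPA1 (AT2G26300), 0.93 for the beta subunit gene AGB1 (AT4G34460) and 1.05 for AGG1 (AT3G63420). The other gamma subunit genes AGG2 (AT3G22942) and AGG3 (AT5G20635) were at -0.43 and -1.29. XLG2 (AT4G34390) and XLG1 (AT2G23460), extra-large alpha subunits, were at 1.79 and 0.66. XLG3 (AT1G31930) was at 0.29, lost its call with quantile normalization (0.11) and turned to -0.04 with upper-quartile scaling. RGS1 (AT3G26090), on a locus joined with a neighbour, was at 0.89.

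Nuclear photosynthesis genes were higher after NAE 18:3 on the deposited scale, while 11 of 13 root markers were lower (median -0.79). All 27 loci tested rose, 24 of them at least 2-fold, with a median of 1.68 (camera adjusted p = 1.0e-09, and adjusted p = 0.219 with an estimated correlation), but with quantile normalization 16 rose, 5 fell and 6 did not pass, the median was 0.17 and the group was no longer called. The 10 loci that turned in sign there were LHCB1.1, LHCB1.2, LHCB1.3, LHCB3, PSAD1, PSAF, PSAG, PSBP1, RBCS1A and the joined locus of RBCS1B, RBCS2B and RBCS3B. LHCB2.1 (AT2G05100), a light-harvesting protein of photosystem II, rose from 808 ± 4.56 to 4552 ± 138 FPKM and LHCA3 (AT1G61520), of photosystem I, from 1303 ± 11.4 to 4745 ± 32.3 FPKM, and both were also higher with the other 2 scalings. Chlorophyll biosynthesis genes were mixed and not called (11 rose, 5 fell and 1 did not pass of 17, median 0.61, camera adjusted p = 0.16), and FLU among them turned lower with either of the other scalings. HEMA1 (AT1G58290), glutamyl-tRNA reductase, and GUN5 (AT5G13630), a subunit of magnesium chelatase, rose by 1.74 and 1.46. PORB (AT4G27440) and PORC (AT1G03630), protochlorophyllide oxidoreductases, fell from 504 ± 9.01 to 238 ± 2.23 FPKM and from 139 ± 2.96 to 73.0 ± 1.01 FPKM. Of 8 chlorophyll breakdown loci 7 rose and 1 fell, with a median of 1.28 (camera adjusted p = 0.026, and adjusted p = 0.186 with an estimated correlation), a call also lost with at least 5 FPKM and with joined loci left out. NYC1 (AT4G13250), chlorophyll b reductase, rose from 47.9 ± 2.59 to 285 ± 3.16 FPKM and the locus that holds PAO, pheophorbide a oxygenase, by 1.93, while CLH1 (AT1G19670), a chlorophyllase, fell by 0.44.

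Flavonoid genes fell as a group. Of 9 tested, 9 fell at least 2-fold, with a median of -3.76 (camera adjusted p = 3.7e-05, and adjusted p = 0.128 with an estimated correlation), CHS and LDOX having the smallest adjusted p. Of 14 clock loci 12 rose, 1 fell and 1 did not pass, with a median of 1.48 (camera adjusted p = 0.0012, and adjusted p = 0.186 with an estimated correlation). RVE1 (AT5G17300), a morning MYB-like factor, rose from 1.49 ± 0.0602 to 90.3 ± 2.61 FPKM and the locus that holds PRR7 by 2.34, while LHY (AT1G01060) fell by 0.47, from 2.7 ± 0.0372 to 1.68 ± 0.225 FPKM, a call lost with quantile normalization (-0.18). Light and shade genes were not called (5 rose, 2 fell and 1 did not pass of 8, median 0.62, camera adjusted p = 0.31). There PIL6 (AT3G59060), the phytochrome-interacting factor PIF5, rose by 1.97 and HY5 (AT5G11260) by 0.91, while the shade marker HB-2 (AT4G16780) fell by 0.98 and ELIP1 (AT3G22840) by 0.16.

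Listed genes of the cell cycle, and most of the few ribosomal protein genes on the list, were lower. So were 11 of 13 root markers, among them the root meristem gene PLT1 (AT3G20840, log2 change -1.22), while WOX5 rose (0.67) and 1 did not pass. All 20 cell cycle and replication loci tested fell, with a median of -1.46 (camera adjusted p = 6.0e-07, and adjusted p = 0.128 with an estimated correlation). PCNA1 (AT1G07370), the replication clamp, fell from 37.5 ± 1.14 to 5.61 ± 0.505 FPKM and MCM2 (AT1G44900), of the replicative helicase, from 17.3 ± 0.382 to 3.41 ± 0.137 FPKM. Of 9 tested loci whose description names a 40S or 60S ribosomal protein, a small part of that family, 8 fell and 1 rose, with a median of -1.43 (camera adjusted p = 0.0043, and adjusted p = 0.186 with an estimated correlation). RPL23AA (AT2G39460) fell from 831 ± 9.2 to 203 ± 3.56 FPKM and the locus that holds BBC1 by 2.17, and AT5G02440 rose by 0.68. Of 6 genes of the endoplasmic reticulum unfolded protein response 5 fell and 1 rose, with a median of -1.14 (camera adjusted p = 0.037, and adjusted p = 0.242 with an estimated correlation), a call also lost with no filter and with upper-quartile scaling. The lumenal chaperone genes BIP2 (AT5G42020) and BIP1 (AT5G28540) fell by 1.93 and 1.27, while BZIP60 (AT1G42990), a transcription factor of that response, rose by 1.64. Cell wall expansion genes went both ways (10 rose and 9 fell of 19, median 0.54, camera adjusted p = 0.611). XTH24 (AT4G30270) and XTH23 (AT4G25810) rose by 4.70 and 5.11, while XTH9 (AT4G03210) and XTH31 (AT3G44990), of the same enzyme family, fell by 2.69 and 1.27.

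**Figure D2:**
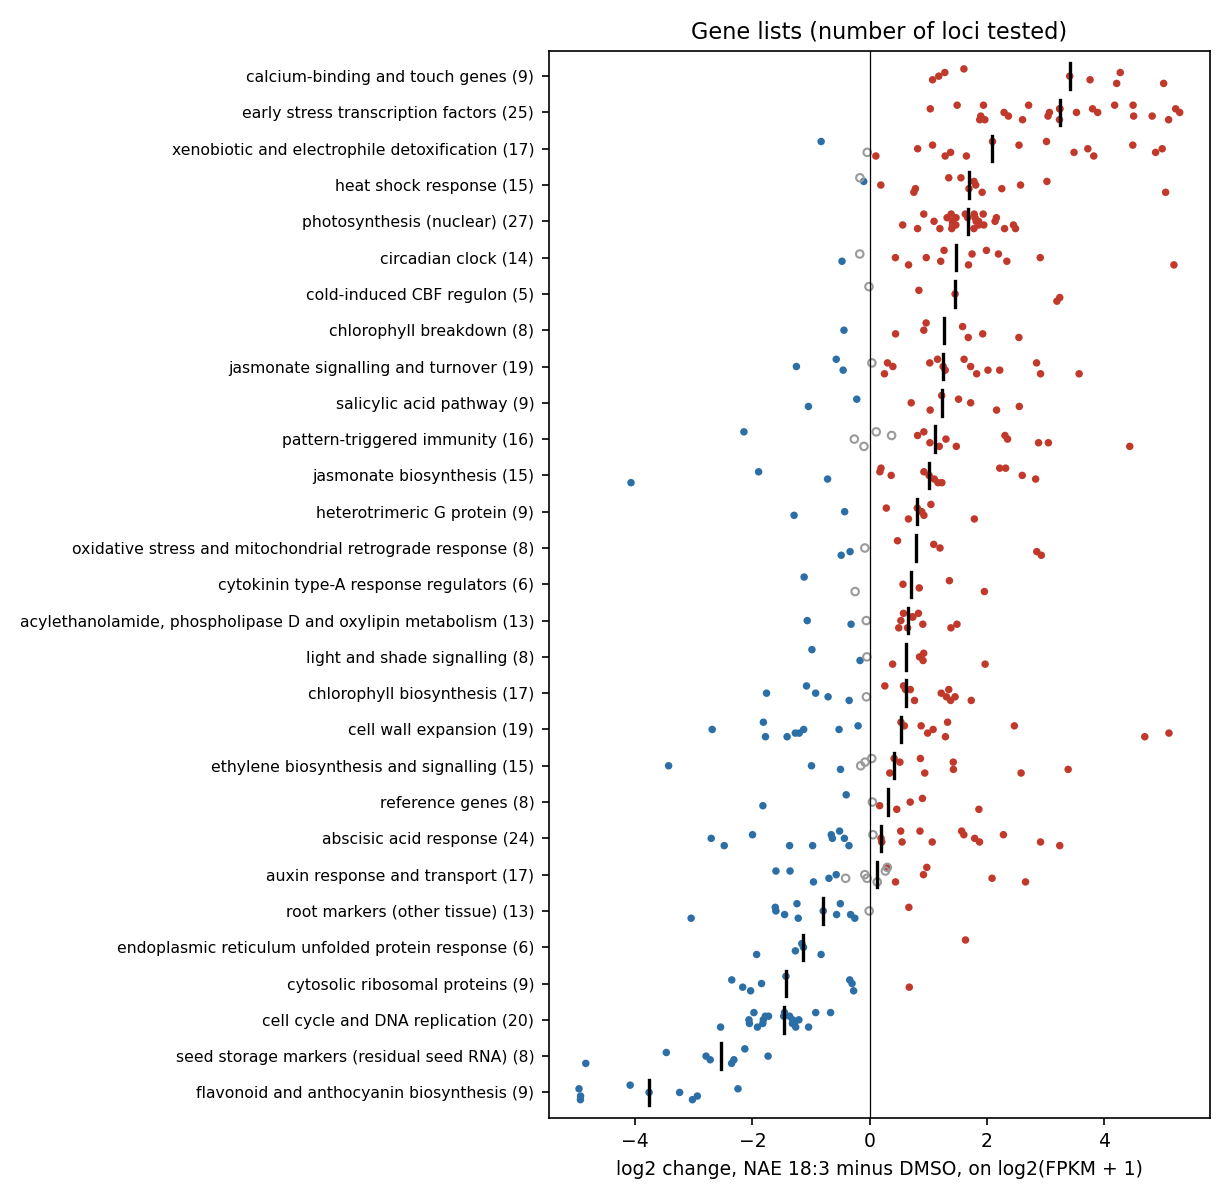
Log2 change (NAE 18:3 minus DMSO on log2(FPKM + 1)) of each tested locus in the 29 gene lists, one list per row with its number of loci, filled points past an adjusted p of 0.05 (red higher, blue lower), open points not past it, and a bar at the list's median. Medians run from -3.76 for flavonoid genes to 3.42 for calcium-binding and touch genes, and the photosynthesis median of 1.68 fell to 0.17 with quantile normalization.

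Markers of tissue and of residual seed RNA moved with the treatment. Of 13 root markers 11 fell, 1 rose and 1 did not pass, with a median of -0.79 (camera adjusted p = 0.013, and adjusted p = 0.174 with an estimated correlation), a call also lost with at least 5 FPKM. PRP3 (AT3G62680), a root hair cell wall protein, fell from 22.8 ± 1.45 to 1.88 ± 0.198 FPKM and CASP1 (AT2G36100), of the endodermal Casparian strip, from 34.4 ± 0.252 to 12.0 ± 1.11 FPKM, while WOX5 (AT3G11260), of the root quiescent centre, rose from 5.71 ± 1.09 to 9.65 ± 1.36 FPKM. Of 8 seed storage markers 8 fell, with a median of -2.54 (camera adjusted p = 0.0021, and adjusted p = 0.186 with an estimated correlation). With CRA1 given above, OLEO2 (AT5G40420), an oil body protein, had the smallest adjusted p and went from 8.22 ± 0.456 to 0.399 ± 0.0485 FPKM. Of 8 genes used as references in expression studies 5 rose, 2 fell and 1 did not pass (median 0.32, camera adjusted p = 0.36), and their median turned to -0.02 with upper-quartile scaling. Their log2 changes ran from -1.82 for EF1A (AT5G60390) to 1.87 for ACT2 (AT3G18780). SAND (AT2G28390) stood at 18.0 ± 0.531 and 18.6 ± 0.36 FPKM. It did not pass on the deposited scale but was called lower with either of the other scalings. With upper-quartile scaling 4 of the reference genes rose, 4 fell and 0 did not pass. TIP41L (AT4G34270) was at 0.17 and turned negative with either of the other scalings.

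**Figure D3:**
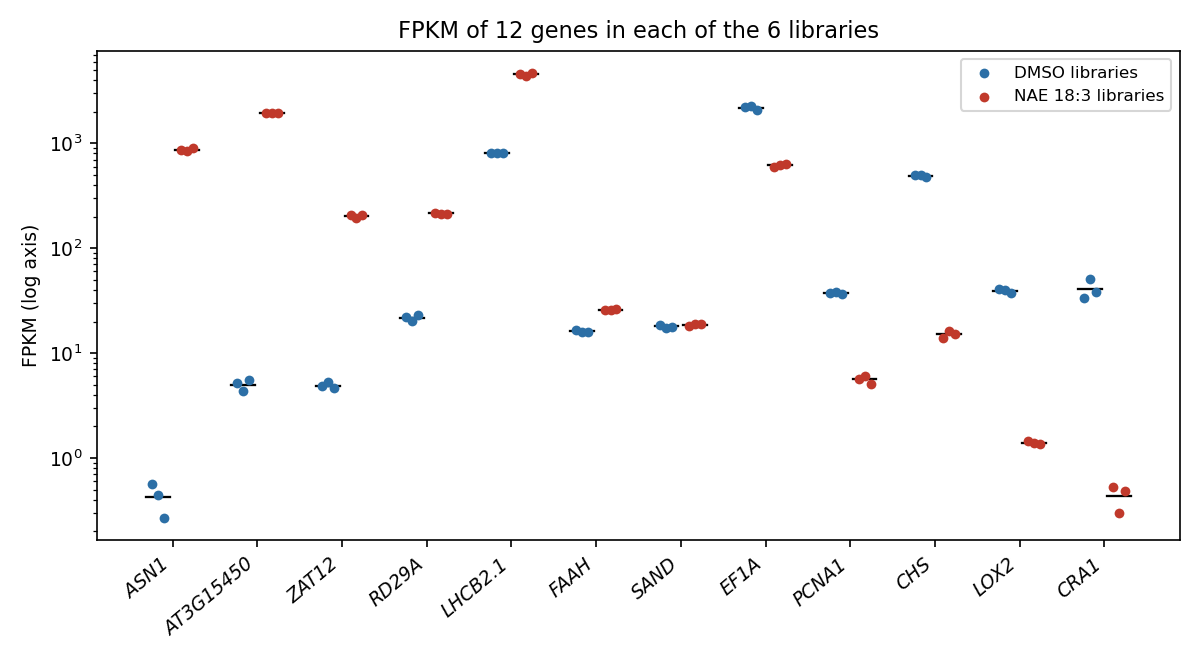
FPKM on a log axis of 12 genes in each DMSO (blue) and NAE 18:3 (red) library, with bars at the group means. The libraries of a group lie close together for ZAT12, LHCB2.1, EF1A, CHS and LOX2, with the groups far apart. For ASN1 the groups are also far apart, but its DMSO libraries ranged from 0.270 to 0.566 FPKM. SAND has group means of 18.0 and 18.6 FPKM.

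With 17 of the 29 lists called by camera with the preset correlation, 0 were called once the correlation was estimated from these 6 libraries, and the adjusted p of those 17 then ran from 0.128 to 0.433. For detoxification (-0.045), chlorophyll breakdown (-0.024), jasmonate signalling (-0.020), root (-0.019) and acylethanolamide (-0.016) the estimate was below the preset 0.01. A correlation above the preset is therefore not what ended those calls. For detoxification the unadjusted camera p went from 6.0e-05 to 0.012 although the estimated correlation was lower than the preset. The setting thus raised p-values in some other way too. How much of the loss at the remaining lists came from correlation was not tested. The counts of single members that rose or fell do not depend on the correlation used.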

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

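Summing transcripts per TAIR gene and leaving out loci over several TAIR genes were alternatives chosen after the data were seen. The number of changed loci, 15143, became 15090 with a pseudocount of 0.1, 16840 with no filter, 11702 with a mean of at least 5 FPKM, 14987 with quantile normalization and 15354 with upper-quartile scaling. It was 15084 with no trend, 15127 with a robust trend, 13912 at an adjusted p under 0.01, 15203 with transcripts summed and 14670 with joined loci left out. A 2-fold minimum left 6480, with 3347 higher and 3133 lower. Without 1 library at a time it ran from 14616 to 15004. Quantile normalization gave 7243 higher and 7744 lower, and shared 13661 changed loci with the deposited scale, where upper-quartile scaling shared 13334. Of the alternative values of single named genes, 1938 were counted as unchanged, 8 lost the call and 3 reversed. A named gene not called on the deposited scale, such as SAND, also counted as unchanged when its sign turned, whatever its new p-value. The reversals were TIP41L, at -0.0719 with quantile normalization and -0.16 with upper-quartile scaling, and XLG3, at -0.0407 with upper-quartile scaling; the shift of all loci by that scaling exceeds these changes. LHY (-0.18) and XLG3 (0.11) lost their calls with quantile normalization, and ROF1 with no trend, with the block and without any of 4 libraries. Values near the floor of 1 FPKM are limited by depth, most of all in DMSO replicate 1.

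Of the alternative values of the lists, 467 were counted as unchanged, 20 gained a call and 33 lost one. An uncalled list that turned in direction and stayed uncalled also counted as unchanged. With no filter the CBF regulon (0.63), ethylene (0.52) and G protein (0.82) lists were called and the unfolded protein response (-1.13) was not. With at least 5 FPKM, where fewer members are tested, the acylethanolamide (0.69), chlorophyll breakdown (0.97), jasmonate biosynthesis (0.97) and root (-0.29) lists were lost. Quantile normalization called the CBF regulon (1.64) and lost jasmonate biosynthesis (0.65) and photosynthesis (0.17). Upper-quartile scaling called the CBF regulon (1.201) and salicylic acid (0.92) and lost the unfolded protein response (-1.49). Summing transcripts lost jasmonate biosynthesis (1.02), and leaving out joined loci lost it (1.02) and chlorophyll breakdown (1.28). Without 1 library at a time, jasmonate biosynthesis ran from 1.00 to 1.04 and was lost in 3 cases, and the CBF regulon ran from 1.34 to 1.56 and was called in 2 cases. Apart from the tests on fewer members, the cause was not tested.

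With an estimated correlation the calls ended for early stress factors (3.24), calcium and touch (3.42), detoxification (2.099), heat shock (1.70), photosynthesis (1.68), the clock (1.48), chlorophyll breakdown (1.28), jasmonate signalling (1.26), pattern-triggered immunity (1.11), jasmonate biosynthesis (1.02), acylethanolamide (0.65), root (-0.79), the unfolded protein response (-1.14), ribosomal proteins (-1.43), the cell cycle (-1.46), seed storage (-2.54) and flavonoids (-3.76). Fry, which compares a list with no change and not with other loci, also called abscisic acid (0.20), auxin (0.13, upward where camera gave a downward direction), the cell wall (0.54), chlorophyll biosynthesis (0.61), the CBF regulon (1.46), cytokinin (0.71), ethylene (0.42), G protein (0.82), light (0.62), oxidative stress (0.79), reference genes (0.32) and salicylic acid (1.23).

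The libraries share only replicate numbers, and these do not pair them: r of the residuals was -0.01, -0.01 and 0.02 for equal numbers. A replicate block changed the count to 15012, 7951 higher and 7061 lower, and lost acylethanolamide (0.65) and jasmonate biosynthesis (1.02).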

Other observations

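The 6 lists of the next 2 paragraphs were drawn up after the largest changes had been seen and leave out the loci seen; their p-values are adjusted over these 6. Of 13 tested carbon-starvation-induced genes 13 rose, with a median log2 change of 4.28 (limma camera, Benjamini-Hochberg adjusted p = 4.0e-07, and adjusted p = 0.028 with an estimated correlation). SEN1 (AT4G35770), a senescence and darkness gene, went from 28.4 ± 1.04 to 1294 ± 18.9 FPKM and DIN10 (AT5G20250), of raffinose metabolism, from 22.0 ± 1.46 to 1035 ± 18.3 FPKM (mean ± SD, n = 3 each). BT2 (AT3G48360) rose by 5.604 and GDH2 (AT5G07440), glutamate dehydrogenase, from 64.3 ± 2.99 to 925 ± 2.9 FPKM. TPS9 of this list was not analysed here. Of 9 branched-chain amino acid breakdown genes 9 rose, with a median of 2.73 (camera adjusted p = 0.00012, and adjusted p = 0.030 with an estimated correlation), among them MCCA (AT1G03090), from 5.41 ± 0.467 to 157 ± 1.44 FPKM. Of 15 autophagy genes 13 rose and 2 did not pass, with a median of 0.98 (camera adjusted p = 0.0011, and adjusted p = 0.034 with an estimated correlation), of which ATG8D was lower with upper-quartile scaling. ATG8E (AT2G45170) rose from 10.2 ± 1.73 to 172 ± 3.19 FPKM.

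All 11 tested ribosome biogenesis genes fell, with a median of -2.08 (limma camera, Benjamini-Hochberg adjusted p = 2.5e-06, and adjusted p = 0.034 with an estimated correlation). NOP56 (AT1G56110), a nucleolar protein, went from 153 ± 5.15 to 13.9 ± 0.446 FPKM and NUC1 (AT1G48920), nucleolin, from 370 ± 12.9 to 72.4 ± 0.749 FPKM. All 10 aliphatic glucosinolate biosynthesis genes tested fell, with a median of -2.71 (camera adjusted p = 3.7e-05, and adjusted p = 0.030 with an estimated correlation). CYP83A1 (AT4G13770) went from 16.4 ± 0.13 to 0.279 ± 0.106 FPKM. Of 5 sugar-induced genes 4 fell and 1 rose, and the list was not called (median -1.48, camera adjusted p = 0.10). APL3 (AT4G39210), of starch synthesis, fell from 26.2 ± 1.04 to 1.301 ± 0.0929 FPKM, while SBE2.2 (AT5G03650) rose by 0.95.

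In the paragraphs that follow, the tests on scaling, on the shallowest library, on a level-dependent difference, on gene length bias and root share as the only cause, on handling and on the falls within 1 h were chosen only after the results were seen. Photosynthesis genes were higher and root markers lower after NAE 18:3. Against a scaling factor per library as the whole cause, the photosynthesis median was still 1.32 after upper-quartile scaling, and against the shallowest library it was 1.68 without DMSO replicate 1. With a smaller share of root tissue as the only cause, abundant shoot genes were predicted to rise alike. Instead, 3 chlorophyll biosynthesis genes fell at least 1.5-fold, PORB (-1.08), PORC (-0.92) and GSA1 (-0.71), which root share alone does not explain. On the deposited scale 0 of 27 photosynthesis loci fell, against 39.2% of all loci. The test therefore does not decide the question for the photosynthesis list. Root share may still contribute, as 7.69% of root markers rose, and whether it also bears on the fall of cell cycle and ribosomal genes was not tested. A level-dependent difference between the libraries also stays open, because the median of 0.17 after quantile normalization is fixed in part by the ranks of these 27 abundant loci. Bias by annotated gene length as the only cause is argued against by 0 of 100 lists matched on length and level that reached the photosynthesis median of 1.66 (highest 1.36). The r between log2 change and log2 length was 0.018. A part stays open, as only 74 of the matched lists had a median less than 0.5 times that of the photosynthesis list. The matched lists themselves rose, with a median of 0.63. Matching on both cannot separate length from level, and transcript length was not tested. All 27 photosynthesis loci were among the 200 most abundant of both groups, where few other loci remain to match. The match in level may therefore be loose, and its closeness was not tested.

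ASN1, a dark-inducible gene, had the largest rise of the called loci on the log2(FPKM + 1) scale, although AT2G44130, listed at 0 in DMSO, passed it with a pseudocount of 0.1 (12.2 against 10.7). A transcript response like that of carbon limitation is consistent with the second list, of which 100% rose, although the medium of both groups held sucrose by the labels and sugar levels were not measured. For a different time of day at harvest, morning genes were predicted to move together, and evening genes together in the opposite direction. Instead, 4 of 9 morning-evening pairs changed in one direction, as CCA1, PRR9, TOC1 and LUX all rose. With 44.1% of all loci higher and 39.2% lower, such pairs can be common whatever the time of day. The test therefore cannot decide on a shift in time of day, which stays open. The morning genes CCA1 (1.75) and LHY (-0.47) went opposite ways, and of 14 clock loci 12 rose, 1 fell and 1 did not pass. Handling of the groups other than the compound stays open, since 0 libraries in the labels separate it from NAE 18:3.

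Some transcripts fell too deeply for slow decay within 1 h. At 58 of the 8881 loci with at least 10 FPKM in every DMSO library, the lowest DMSO value was at least 16 times the highest NAE 18:3 value, and 2 of the 58 were listed at 0 after NAE 18:3. Without any new synthesis a 16-fold fall requires a half-life of 15 min or less. For CRA1 the longest half-life allowed is 10.0 min, and for AT5G26220 it is 7.69 min. Decay during the 1 h and a difference between the groups before the treatment cannot be told apart here: seed storage transcripts had a median log2 change of -2.54, but no untreated library and no decay rate was among the values analysed. The conclusion that every change arose within the hour is therefore open.

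For the number of changed loci, the 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05; the real split gave 15143, the highest other 0, and 1 split gave as many as the real one, itself.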
